A study of Homo sapiens with 12 samples.

How the data were processed

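The 12 libraries were polyadenylated RNA made with the TruSeq stranded mRNA kit and sequenced on an Illumina HiSeq instrument, per the labels. The deposited values are raw counts of reads per gene that the authors made for each library, 1 file per library. The submitters' processing notes name TopHat2 2.0.13 for alignment, HTSeq for counting and the genome build GRCh37; the HTSeq version, the annotation release, the strand setting and any filter are not given in the sources used here, so reads of overlapping or antisense genes may be shared. Each file held 57773 Ensembl gene identifiers with whole-number counts and 0 summary lines of unassigned reads. Gene symbols, gene types, chromosomes, GC content and length came from GENCODE release 29 on GRCh38, used only for such properties; 52338 identifiers were found there and 51996 received a symbol.

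Groups followed the labels: E, E/M, xM, ZKO, ZKO_Sn and ZKO_Sn_Zmt, with 2 libraries each. Totals ran from 37319802 to 57073811 counts, so 3 counts, the limit that a count of 0 allows, corresponded to at most 0.0814 CPM, the read count scaled to library size and TMM factor. Libraries were scaled by TMM in edgeR 4.0.16 on R 4.3.3, genes were kept by edgeR's filterByExpr, and 17058 were tested (18016 without the library labelled ZKO_Sn_Zmt replicate 1). A single model with 1 mean per group was fitted over all 12 libraries, with 6 residual degrees of freedom and a biological coefficient of variation of 0.358, and contrasts were tested with the quasi-likelihood F test and Benjamini-Hochberg correction at 0.05. The contrasts were E/M against E, xM against E/M, xM against E, ZKO_Sn against ZKO, ZKO_Sn_Zmt against ZKO_Sn, ZKO against E, ZKO_Sn against E/M, ZKO_Sn_Zmt against xM, and the differences of the hybrid and of the mesenchymal step between the series. Standard errors of log2 fold changes come from this model, and group means carry the SD of the 2 libraries. For genes with 3 counts or fewer in the lower group, at-least folds were computed against 3 counts per library, and ratios with exact 95% Clopper-Pearson binomial intervals.

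From gene lists written from general knowledge, 24 in number with 439 entries of which 2 were not matched by symbol, each list was tested with camera of limma 3.58.1 with its preset correlation, with a correlation estimated per list, and with fry, and corrected over the lists of a contrast. The comparisons, groups, lists, main settings, most alternatives and the rule for naming genes were fixed before the data were examined. By that rule ZEB1, SNAI1, CD44, ITGB4, CDH1 and VIM could be named everywhere. For each step up to 6 rising and 6 falling protein-coding genes were taken by size of change, among those with an adjusted p under 0.05, CPM that did not overlap between the groups and a mean of at least 10 CPM in the higher group; for the other contrasts up to 4 each way. For each called list, and a few lists always, up to 4 members with an adjusted p under 0.05 and at least 1 CPM were taken, and for genes highest or lowest in E/M 6 each way by the smaller of their 2 changes. The rule was also applied to the fit without the library labelled ZKO_Sn_Zmt replicate 1 for the Snail step, the rescue step and the difference at the mesenchymal step, which was chosen after seeing the data; genes named outside the rule, such as single members of a list, were chosen after their values were seen.

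Alternatives set beforehand were RLE scaling, no filter on low counts, a stricter filter, DESeq2 1.42.0, a test against a 2-fold change with glmTreat, a fit of only the groups compared, replicate number as a block, rank correlation, fry, the estimated correlation, and leaving out each library in turn. Chosen after seeing the data were a fit without the library labelled ZKO_Sn_Zmt replicate 1 for contrasts that do not use it, the removal of each library's trend with GC content and length, and leaving out single libraries for the named genes. The pipeline was tested on simulated data: with 50 genes changed at each fold in counts modelled on these libraries, E/M against E recovered 4% of 2-fold, 62% of 4-fold, 90% of 8-fold and 94% of 16-fold changes with 6 false calls, and in 20 draws with no difference the mean was 0.1 false calls. The simulated counts of a gene had the same spread in all groups and no bias with GC content or length. They cannot show recovery or false calls where groups differ in spread, as real replicate distances did, from 0.308 in xM to 0.964 in E/M. Reads, splicing and sequence variants were not analysed here, and no gene coordinates are given, since the counts and the annotation are on different genome builds.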

Results

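Messenger RNA was sequenced in 12 libraries from human mammary epithelial cells, which the labels call HMLER, the RAS-transformed line, and the series text calls HMLE, its immortalised parent; the labels are followed here. The libraries fell into 6 groups of 2, and the labels call the second library of each group a duplicate without saying whether it came from a separate culture. The sorted groups were an epithelial population (E), a hybrid population (E/M) and an extreme mesenchymal population (xM), separated by surface CD104 (ITGB4) and CD44. The engineered groups came from a single-cell clone: ZKO (xE-SCC-Zeb1KO) lacks Zeb1, ZKO_Sn (E-SCC-Zeb1KOSn) also received Snail (SNAI1), and ZKO_Sn_Zmt (E-SCC-Zeb1KOSnZmt) also received a CRISPR-resistant Zeb1. The label of xM repeats the sorting gate given for E/M, and the labels put all engineered groups in the epithelial state although the series text describes ZKO_Sn as hybrid and ZKO_Sn_Zmt as mesenchymal. CD44 and ITGB4 were sort markers, so their levels are not findings.

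Total counts were 41254450 and 39745660 for E replicates 1 and 2, 45498907 and 38986051 for E/M, and 44840941 and 41334866 for xM. In the engineered series they were 48251083 and 43080402 for ZKO, 43568057 and 37319802 for ZKO_Sn, and 49737180 and 57073811 for ZKO_Sn_Zmt. A floor of 3 counts corresponded to between 0.0508 and 0.0814 CPM, the read count scaled to library size with TMM factors. Mitochondrial transcripts took 0.6 to 0.95% of counts in the 6 first replicates and 1.3 to 2.49% in the 6 second replicates. In a principal component analysis, component 1 carried 59.4% of the variance and component 2 carried 12.6%. E, ZKO, ZKO_Sn and the library labelled ZKO_Sn_Zmt replicate 1 lay on the negative side of component 1, and E/M, xM and ZKO_Sn_Zmt replicate 2 on the positive side.

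**Figure D1:**
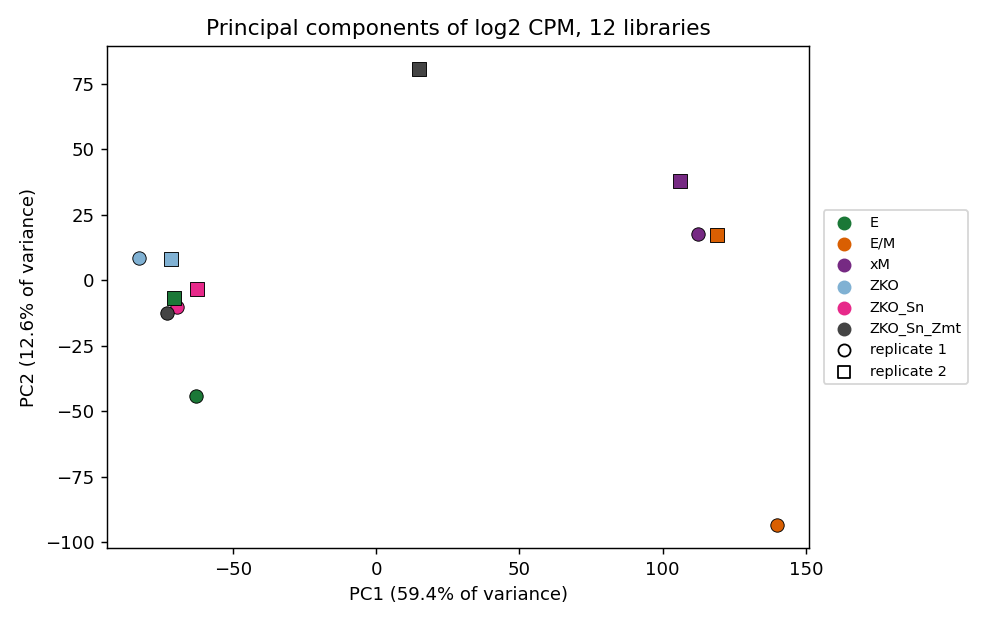
Principal components 1 (59.4% of variance, x axis) and 2 (12.6%, y axis) of log2 CPM for the 12 libraries; colours mark the 6 groups, circles replicate 1 and squares replicate 2. E/M and xM lie at 106.21 or more on component 1, the library labelled ZKO_Sn_Zmt replicate 1 at -73.05 beside ZKO_Sn, and ZKO_Sn_Zmt replicate 2 at 15.16.

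ZEB1, the zinc-finger repressor of epithelial genes that was knocked out and put back, had 3 and 19 counts (0.075 and 0.426 CPM) in E replicates 1 and 2. It had 238 and 468 counts (6.45 and 11.5 CPM) in E/M, and 907 and 791 counts (20.6 and 18.4 CPM) in xM. In the knockout clone ZKO it had 78 and 16 counts (1.58 and 0.357 CPM), and in ZKO_Sn 7 and 8 counts (0.163 and 0.217 CPM). The library labelled ZKO_Sn_Zmt replicate 1 held 8 ZEB1 counts (0.163 CPM), the level of ZKO_Sn, whereas replicate 2 held 10449 counts (177 CPM). By the root-mean-square log2 difference over 9466 genes, the nearest library to the library labelled ZKO_Sn_Zmt replicate 1 was ZKO_Sn replicate 1 at a distance of 0.241, closer than the 2 ZKO_Sn libraries were to each other (0.375). Its distance to ZKO_Sn replicate 2 was larger, at 0.52 by a closely related measure without median centring. Comparisons with ZKO_Sn_Zmt are therefore given with all 12 libraries and without the library labelled ZKO_Sn_Zmt replicate 1. The second form had been set beforehand for counts and lists of the comparisons that use this library, and was extended to single genes and to the other comparisons after seeing the data.

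CDH1, the adherens junction protein E-cadherin, averaged 216 ± 23.6 CPM in E (SD, n = 2, as for all group means), 0.643 ± 0.41 in E/M, 0.462 ± 0.204 in xM, 281 ± 3.09 in ZKO and 193 ± 27.2 in ZKO_Sn. It stood at 152 CPM in the library labelled ZKO_Sn_Zmt replicate 1 and 9.29 CPM in replicate 2. VIM, the mesenchymal intermediate filament vimentin, averaged 1070 ± 82.1, 3790 ± 1390, 5030 ± 175, 1130 ± 43.1 and 1500 ± 91 CPM in those 5 groups, and stood at 1510 and 4570 CPM in the libraries labelled ZKO_Sn_Zmt replicates 1 and 2. SNAI1, the Snail gene, averaged 1.04 ± 0.297 CPM in E, 3.99 ± 2.52 in E/M, 2.51 ± 0.112 in xM, 0.667 ± 0.0597 in ZKO and 2.54 ± 1.48 in ZKO_Sn, with 2.83 and 4.7 CPM in the libraries labelled ZKO_Sn_Zmt replicates 1 and 2. Counts per gene do not separate introduced Snail from the cells' own SNAI1, so expression of the introduced Snail is not established here. Of the sort markers, ITGB4 averaged 581 ± 247 CPM in E, 255 ± 49.2 in E/M and 5.22 ± 0.0659 in xM, and CD44 707 ± 42.5, 810 ± 406 and 883 ± 35 CPM.

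**Figure D2:**
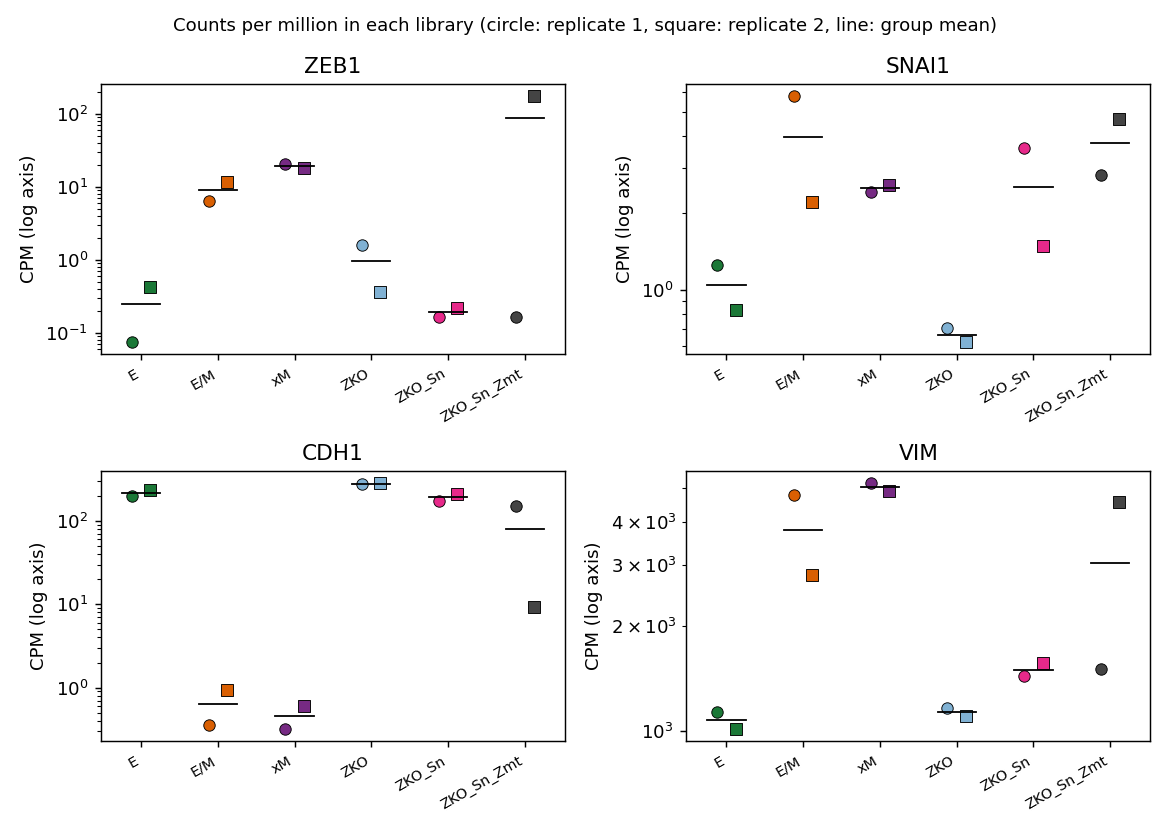
CPM (log axis) of ZEB1, SNAI1, CDH1 and VIM in each library of the 6 groups; circles are replicate 1, squares replicate 2 and lines group means. The library labelled ZKO_Sn_Zmt replicate 1 has 0.163 CPM of ZEB1 and 152 CPM of CDH1, against 177 and 9.29 CPM in replicate 2.

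E/M was compared with E to find what the hybrid state gained and lost relative to the epithelial state. Its CDH1 level fell by 8.38 ± 1.17 on the log2 scale (SE; adjusted p = 0.00119). Each adjusted p of a gene is from edgeR's quasi-likelihood test with Benjamini-Hochberg correction unless another tool is named. KRT14, the basal keratin, fell by 12.32 ± 1.70 (adjusted p = 0.00113), and KRT5, its partner keratin, fell by 11.46 ± 1.31 (adjusted p = 0.000403). TP63, the regulator of basal epithelial identity, fell by 10.34 ± 1.35 (adjusted p = 0.000795). EPCAM, an epithelial adhesion molecule, fell by 9.52 ± 1.21 (adjusted p = 0.000675). ESRP1, the epithelial splicing regulator, fell by 10.13 ± 1.51 (adjusted p = 0.00166). GRHL2, an epithelial transcription factor that represses ZEB1, had 0 counts in E/M and was at least 479-fold lower than in E, where it averaged 37.1 CPM. CBLC, a ubiquitin ligase gene, was at least 454-fold lower, and DAPP1, an adaptor gene of the PI3K pathway, at least 519-fold lower. LAD1, a basement-membrane protein gene, had 11579 counts in E and 1 in E/M, a ratio of 10600 (95% counting interval 1910 to 420000). These intervals are exact Clopper-Pearson binomial intervals, and they and the floors of 3 counts per library cover counting error only.

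CRMP1, which acts on the cytoskeleton in axon guidance, rose from 3 counts in E to 5470 in E/M, a ratio of 1990 (680 to 9640; adjusted p = 3.05e-05). RTN1, a reticulon of the endoplasmic reticulum, rose with a ratio of 1650 (456 to 13600; adjusted p = 0.000207), and DCN, the matrix proteoglycan decorin, with a ratio of 1340 (240 to 53000; adjusted p = 0.00308). COL6A2, a collagen VI chain, rose by 6.39 ± 0.93 on the log2 scale (adjusted p = 0.00154). Other matrix genes fell: TIMP3, a metalloproteinase inhibitor, fell by 6.00 ± 0.91 (adjusted p = 0.00181) and COL5A2, a collagen V chain, fell by 6.00 ± 1.09 (adjusted p = 0.00457; 0.0521 without E/M replicate 1). Of 25 measured matrix genes 7 rose and 3 fell (8 and 6 adjusted over the list alone), and the list was not called (camera adjusted p = 0.302). VIM rose by 1.82 ± 0.46 (adjusted p = 0.0214) with all libraries, and was not called without E replicate 1 (0.0903), E/M replicate 1 (0.117) or E replicate 2 (0.132), or in a fit of only E and E/M (0.0782). ZEB1 was higher by 5.12 ± 1.92 and did not pass (adjusted p = 0.0894) while the disparate ZKO_Sn_Zmt libraries entered its spread; without the library labelled ZKO_Sn_Zmt replicate 1 the same difference had an adjusted p of 0.000527. SNAI1 rose by 1.94 ± 0.59 (adjusted p = 0.0461), a call lost without E replicate 1 (0.119), E/M replicate 1 (0.281) or E replicate 2 (0.242), or in that smaller fit (0.096).

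Of 17058 genes tested, 2848 changed between E/M and E, 1399 higher and 1449 lower, and 2788 of them had a fitted change of more than 2-fold. A test against a 2-fold change called 1163, 473 higher and 690 lower. Dropping E/M replicate 2 gave 5632, whereas dropping E replicate 1, E/M replicate 1 or E replicate 2 gave 1187, 1457 and 815. The p-values throughout measure only the spread between these samples, which may be technical if the duplicates share a culture. The 2 E/M libraries differed from each other more than the 2 libraries of any other group, at a distance of 0.964 against 0.851 or less.

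The epithelial adhesion and polarity list had 24 measured genes, of which 0 rose, 21 fell and 3 did not pass (0 and 23 adjusted over the list alone). Its camera adjusted p was 7.37e-20, with adjusted p = 0.207 with an estimated correlation. MAL2, an apical sorting protein gene, fell by 10.83 ± 1.41. Among 16 epithelial transcription and splicing regulators 12 fell and 1 rose (14 and 1 adjusted over the list alone). The camera adjusted p was 4.6e-12, with adjusted p = 0.207 with an estimated correlation. TFAP2C, an AP-2 factor, was the riser at 1.65 ± 0.36 (adjusted p = 0.0115). Of 15 basal keratins and basal mammary markers 9 fell (12 adjusted over the list alone; camera adjusted p = 1.53e-10). Of 12 desmosome genes 7 fell (9 adjusted over the list alone; camera adjusted p = 3.12e-08). Both had adjusted p = 0.207 with an estimated correlation. DSG3, a desmosomal cadherin, fell by 8.91 ± 1.38. Of 12 luminal mammary markers 6 fell (2 up and 6 down adjusted over the list alone; camera adjusted p = 0.00279, adjusted p = 0.249 with an estimated correlation). SPDEF, a luminal transcription factor, fell by 7.62 ± 1.05. Of 12 epidermal cornification genes 5 fell (8 adjusted over the list alone; camera adjusted p = 0.000953, adjusted p = 0.415 with an estimated correlation). Of 10 hemidesmosome genes 4 fell, as they did adjusted over the list alone (camera adjusted p = 0.00312, adjusted p = 0.279 with an estimated correlation). Without E/M replicate 2 those 2 lists were not called (0.0576 and 0.103).

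Of 23 mesenchymal cell markers 10 rose and 1 fell in E/M against E (12 and 3 adjusted over the list alone; camera adjusted p = 0.00143, adjusted p = 0.396 with an estimated correlation). FAP, a fibroblast activation protease, was the faller, by 4.21 ± 0.76 (adjusted p = 0.00446). Of 21 interferon-stimulated genes 10 fell (1 up and 12 down adjusted over the list alone; camera adjusted p = 0.000178, adjusted p = 0.207 with an estimated correlation). IFIH1, the gene of the cytosolic RNA sensor MDA5, fell by 3.83 ± 0.69. Of 14 canonical Wnt targets 4 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.0135, adjusted p = 0.207 with an estimated correlation). That call was lost without E replicate 2 (0.0535) or the library labelled ZKO_Sn_Zmt replicate 1 (0.0662). RNF43 was the faller, with 526 counts in E and 2 in E/M, a ratio of 241 (66.5 to 2000), a call lost without E/M replicate 1. SFRP1, a secreted Wnt antagonist from the non-canonical Wnt list, which was not called, fell by 4.55 ± 0.61 (adjusted p = 0.000947). Of 16 inflammatory cytokines and NF-kB targets 5 fell (1 up and 6 down adjusted over the list alone; camera adjusted p = 0.0152, adjusted p = 0.415 with an estimated correlation). The call was lost without E replicate 1 (0.227) or E/M replicate 2 (0.198). TNF, the inflammatory cytokine, had 1630 counts in E and 1 in E/M, a ratio of 1500 (268 to 59100).

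Of 6 measured endothelial markers 3 rose and 0 fell in E/M against E, as they did adjusted over the list alone (camera adjusted p = 0.000953, adjusted p = 0.207 with an estimated correlation). The risers were ESAM, whose call was lost without E replicate 1 (0.165), E replicate 2 (0.12) or E/M replicate 1 (0.0767) or in a fit of only E and E/M (0.11), ROBO4 at 4.39 ± 0.61 and KDR, a VEGF receptor gene, at 4.07 ± 0.69. CDH5, the endothelial cadherin, had at most 3 counts in any of the 12 libraries. The 13 mitochondrially encoded genes, which can mark RNA quality, were shifted up as a list (camera adjusted p = 0.0297, adjusted p = 0.651 with an estimated correlation) with 0 genes called, and 0 adjusted over the list alone. This call was lost without E replicate 1 (0.32), E/M replicate 2 (0.591) or the library labelled ZKO_Sn_Zmt replicate 1 (0.0508). Leukocyte markers, cholesterol synthesis genes, non-canonical Wnt genes and the EMT transcription factors as a list were not called in any of the 6 comparisons tested with lists when all 12 libraries were used; the EMT factors were higher in xM than in E/M without the library labelled ZKO_Sn_Zmt replicate 1 (0.0202, and 0.367 with an estimated correlation). With an estimated correlation and all 12 libraries, 0 of the 48 list calls held. Without the library labelled ZKO_Sn_Zmt replicate 1, 6 of the E/M lists did. The adjusted p was then 0.00165 for adhesion, 0.0103 for desmosomes, 0.0106 for epithelial regulators, 0.0128 for basal markers, 0.0387 for luminal markers and 0.045 for mesenchymal markers.

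**Figure D3:**
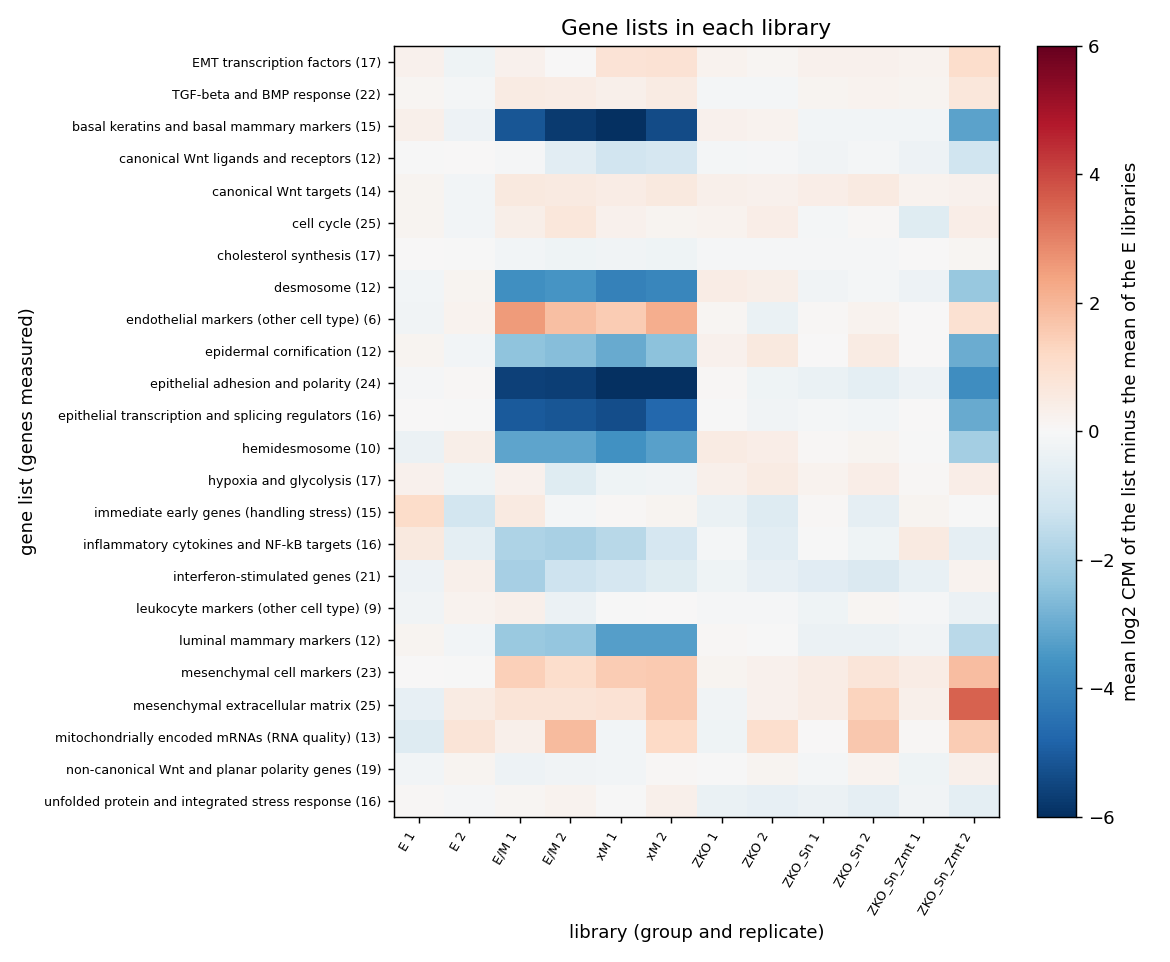
Heat map of 24 gene lists (vertical axis) in 12 libraries (horizontal axis); colour is the mean log2 CPM of the list minus its mean in the E libraries, from -6 to 6. The epithelial adhesion and polarity list lies between -6.34 and -5.62 in E/M and xM, at -3.73 in ZKO_Sn_Zmt replicate 2 and at -0.57 or above in the other engineered libraries, including the library labelled ZKO_Sn_Zmt replicate 1 at -0.29.

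xM was compared with E/M to find what separates the 2 states that had both lost epithelial genes. ROBO1, a receptor for the guidance cue SLIT, rose by 5.20 ± 0.52 on the log2 scale (adjusted p = 0.00432), NPTX2, a secreted neuronal pentraxin, by 8.58 ± 0.89 (adjusted p = 0.00559) and TMPRSS15, the protease enteropeptidase, by 8.17 ± 0.90 (adjusted p = 0.00559). TMPRSS15 averaged 41.3 ± 15.8 CPM in E, 0.0995 ± 0.102 in E/M and 30.2 ± 14.9 in xM. BCAT1, named below, averaged 26.2 ± 1.56, 2.58 ± 0.657 and 34.8 ± 12.9 CPM. Their rises thus came back to near the E level. NPTX2, at 0.0586 ± 0.0122, 0.272 ± 0.0373 and 105 ± 9.32 CPM, was low in both E and E/M. MISP, an actin-binding spindle protein, fell by 4.29 ± 0.44 (adjusted p = 0.00432; 0.061 without xM replicate 2). BCAT1, a branched-chain amino acid transaminase, rose by 3.75 ± 0.46 (adjusted p = 0.00559; 0.0542 without xM replicate 2 and 0.0506 in a fit of only xM and E/M). WNT9A, a canonical Wnt ligand, fell by 3.06 ± 0.54 (adjusted p = 0.0331), a call lost without E/M replicate 1 (0.0784), xM replicate 1 (0.339) or xM replicate 2 (0.353), in the smaller fit (0.074) or with GC and length trends removed (0.102). ZEB1 was higher by 1.12 ± 1.54 (adjusted p = 0.74), VIM by 0.41 (adjusted p = 0.665) and CDH1 lower at -0.49 (adjusted p = 0.836), and none of these passed. A fit of only xM and E/M called 18 genes, 10 higher and 8 lower, fewer than the fit over all 12 libraries. In all, 99 genes changed, 63 higher and 36 lower; without E/M replicate 2 there were 2829, and without xM replicate 1 or xM replicate 2 there were 20 and 10. The split was not stable: the fit without the library labelled ZKO_Sn_Zmt replicate 1 gave 364, 185 higher and 179 lower, DESeq2 gave 522, 232 higher and 290 lower, and removing the GC and length trend of each library left 59, 44 higher and 15 lower.

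Among lists, the luminal mammary markers (12 measured) were lower in xM than in E/M with 0 genes passing and 1 up and 4 down adjusted over the list alone. The camera adjusted p was 0.0244, with adjusted p = 0.903 with an estimated correlation and 0.07 without E/M replicate 2. The canonical Wnt ligands and receptors (12 measured) were lower with 0 rising and 1 falling (0 and 3 adjusted over the list alone). Their camera adjusted p was 0.0434, with adjusted p = 0.893 with an estimated correlation, 0.069 without E/M replicate 1 and 0.07 without E/M replicate 2. The interferon-stimulated genes (21 measured) were higher with 0 genes passing and 2 up adjusted over the list alone (camera adjusted p = 0.0434, adjusted p = 0.938 with an estimated correlation). This was lost without E/M replicate 1 (0.183), E/M replicate 2 (0.154) or xM replicate 2 (0.0575).

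To find genes particular to the hybrid state, those that differed from both E and xM in the same direction were counted, and 20 were higher and 52 lower in E/M. GLMP, a lysosomal membrane protein gene, fell by 8.06 ± 0.60 from E to E/M and rose by 4.89 ± 0.56 from E/M to xM. EREG, the EGF-family ligand epiregulin, fell by 4.76 ± 0.51 and rose by 4.15 ± 0.50, and ROBO1 fell by 5.78 ± 0.54 before its rise of 5.20 ± 0.52. In a fit of only xM and E/M the calls between those 2 were lost for GLMP (0.0547), EREG (0.0506) and KCNJ12 (0.0536). KCNJ12, a potassium channel gene, rose by 7.13 ± 0.62 and then fell by 4.17 ± 0.52 (adjusted p = 0.00597 for the fall; 0.106 and 0.135 without xM replicates 1 and 2). CRMP1 rose into E/M as given above and then fell by 3.95 ± 0.50 (adjusted p = 0.00607; 0.11 and 0.0951 without xM replicates 1 and 2). The number higher in E/M was 940 without E/M replicate 2, 7, 10 and 6 without E replicate 1, E/M replicate 1 or E replicate 2, and 0 without either xM library. The number lower was 1209 without E/M replicate 2, 25 without either E library, and 17 and 9 without xM replicates 1 and 2. There were 83 higher and 120 lower without the library labelled ZKO_Sn_Zmt replicate 1. In 20 simulated draws with no difference the highest number was 0. Those draws held no bias shared by the libraries of a group, so they cannot show how many such genes it would give. With GC and length trends removed 7 genes were higher and 35 lower in E/M. Against a 2-fold change the numbers were 5 and 21, by DESeq2 143 and 164, and without a low-count filter 156 and 206. In the engineered series 0 genes of ZKO_Sn were higher and 0 lower than in both ZKO and ZKO_Sn_Zmt, and 2 and 1 without the library labelled ZKO_Sn_Zmt replicate 1. Those numbers are too low to ask whether the 2 series share such genes.

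xM was compared with E as the population sorted furthest towards the mesenchymal state, although E/M lay further from E: E/M libraries stood at 119.08 and 140.07 on component 1 and xM libraries at 106.21 and 112.33. CDH1 fell by 8.87 ± 1.2 (adjusted p = 0.00135). AGR2, a disulphide isomerase of secretory epithelia, was at least 243-fold lower in xM (adjusted p = 0.00235) and FAM83B, a scaffold of MAPK signalling, at least 164-fold lower (adjusted p = 0.00484). RTN1 rose with a ratio of 1950 (539 to 16100) and NPTX2 by 10.72 ± 1.00 (adjusted p = 0.000494). VIM rose by 2.23 ± 0.47 (adjusted p = 0.0113), a call lost without E replicate 1 (0.0736), xM replicate 1 (0.0597), E replicate 2 (0.102) or xM replicate 2 (0.0527). ZEB1 was higher by 6.24 ± 1.99 (adjusted p = 0.0784), and the same difference had an adjusted p of 0.000165 without the library labelled ZKO_Sn_Zmt replicate 1. In total 1600 genes changed, 624 higher and 976 lower; the count without E replicate 1, xM replicate 1, E replicate 2 or xM replicate 2 was 761, 542, 666 and 556. With GC and length trends removed 1157 were higher and 1286 lower, and in a fit of only xM and E 1315 and 1625.

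Of 24 epithelial adhesion and polarity genes 22 fell from E to xM (24 adjusted over the list alone; camera adjusted p = 6.05e-32). Of 16 epithelial regulators 11 fell and 1 rose (15 and 1 adjusted over the list alone; camera adjusted p = 3.1e-16), and of 12 desmosome genes 9 fell (11 adjusted over the list alone; camera adjusted p = 9.91e-16). Of 15 basal markers 10 fell (13 adjusted over the list alone; camera adjusted p = 6.55e-15) and of 12 luminal markers 7 fell (7 adjusted over the list alone; camera adjusted p = 5.35e-08). Of 10 hemidesmosome genes 4 fell (4 adjusted over the list alone; camera adjusted p = 1.38e-05). These 6 lists had adjusted p = 0.102 with an estimated correlation. Of 12 cornification genes 4 fell (9 adjusted over the list alone; camera adjusted p = 7.62e-06, adjusted p = 0.266 with an estimated correlation). Mesenchymal markers rose in 7 of 23 cases (9 up and 1 down adjusted over the list alone; camera adjusted p = 1.13e-05, adjusted p = 0.236 with an estimated correlation). Endothelial markers rose in 2 of 6 cases (3 adjusted over the list alone; camera adjusted p = 0.00205, adjusted p = 0.105 with an estimated correlation). Interferon-stimulated genes fell in 5 of 21 cases (7 adjusted over the list alone; camera adjusted p = 0.00366, adjusted p = 0.266 with an estimated correlation).

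The canonical Wnt targets shifted up in xM against E with 2 rising and 1 falling of 14 (6 and 1 adjusted over the list alone). The camera adjusted p was 0.0064, with adjusted p = 0.102 with an estimated correlation and 0.0523 without the library labelled ZKO_Sn_Zmt replicate 1. The 25 mesenchymal matrix genes shifted up with 4 rising and 1 falling (5 and 3 adjusted over the list alone). Their camera adjusted p was 0.0426, with adjusted p = 0.643 with an estimated correlation, 0.378 without E replicate 1 and 0.0902 without xM replicate 2. The inflammatory genes shifted down with 2 of 16 falling (3 adjusted over the list alone). For these the camera adjusted p was 0.0426, with adjusted p = 0.47 with an estimated correlation, 0.459 without E replicate 1 and 0.168 without xM replicate 1. Without the library labelled ZKO_Sn_Zmt replicate 1, 7 of the xM lists held with an estimated correlation. They were adhesion (0.000242), desmosome (0.00136), epithelial regulator (0.00136), luminal (0.00537), basal (0.00561), mesenchymal (0.0184) and hemidesmosome genes (0.0218).

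ZKO was compared with E to see how a clone without Zeb1 differs from sorted epithelial cells. Clone and genotype cannot be told apart in this comparison. ZEB1 itself was higher by 1.92 ± 1.83 (adjusted p = 1) with 1.58 and 0.357 CPM in ZKO, and a read-count measure of a gene does not show whether its reading frame was disrupted. P3H3, a collagen prolyl hydroxylase, fell by 6.18 ± 0.64 (adjusted p = 0.0128) and EMC10, a subunit of the membrane protein insertase of the endoplasmic reticulum, by 5.17 ± 0.56 (adjusted p = 0.0205, and 0.0551 with replicate number as a block). CGAS, the cytosolic DNA sensor, fell by 7.02 ± 0.84 (adjusted p = 0.0205), and TUB, a tubby-family gene, by 5.48 ± 0.73 (adjusted p = 0.0385). The value of CGAS is a fitted one that depends on the prior count, since it stood at 0 and 0.0669 CPM in ZKO replicates 1 and 2. TSTD1, a sulphurtransferase gene, was at 9.35 and 8.16 CPM in E and 0 in both ZKO libraries (adjusted p = 0.0385). CGAS, TUB and TSTD1 were chosen for naming after their values were seen. Those 5 were the genes called, all lower, and DESeq2 called 29. A fit of only ZKO and E called 42, 16 higher and 26 lower. An unadjusted p under 0.05 was reached by 435 genes. They are fewer than a share of 0.05 of the 17058 tested, which no difference at all would give. Leaving out any of E replicate 1, ZKO replicate 1, E replicate 2 or ZKO replicate 2 gave 0, and the fit without the library labelled ZKO_Sn_Zmt replicate 1 gave 14; on leaving out each of those 4 libraries the adjusted p of P3H3 was between 0.0729 and 0.418 and that of EMC10 between 0.0988 and 0.465. CDH1 differed by 0.38 and was not called.

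Between ZKO and E 5 lists moved, with 0 genes called over all genes and 0 adjusted over the list alone in each. The 15 immediate early genes were lower in ZKO than in E (camera adjusted p = 0.000256, adjusted p = 0.759 with an estimated correlation), but without E replicate 1 they were higher (0.00885). EGR1, a transcription factor induced by growth factors and handling, stood at 317 CPM in that library and 5.65 CPM in E replicate 2. The 16 unfolded protein response genes were lower (camera adjusted p = 0.000256, adjusted p = 0.263 with an estimated correlation). The 17 hypoxia genes were higher (camera adjusted p = 0.00532, adjusted p = 0.759 with an estimated correlation), but not without E replicate 2 (0.733) or ZKO replicate 2 (0.206). The 12 desmosome genes were higher (camera adjusted p = 0.0364, adjusted p = 0.904 with an estimated correlation), but not without E replicate 1 (0.204) or ZKO replicate 2 (0.142). The 21 interferon-stimulated genes were lower (camera adjusted p = 0.0364, adjusted p = 0.759 with an estimated correlation), but not without E replicate 2 (0.955) or ZKO replicate 2 (0.206).

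ZKO_Sn against ZKO asked what Snail does when Zeb1 is absent. The 2 groups also differed over whole chromosomes, and whether they differ in more than Snail was not tested. With GC and length trends removed, the median log2 difference from E on chromosome 3 was 0.25 and 0.29 in ZKO_Sn replicates 1 and 2. In ZKO it was 0.02 and 0.03. Chromosome 7 stood at -0.03 and -0.08 in ZKO_Sn and at 0 and 0 in ZKO. SNAI1 was higher by 1.93 ± 0.57 and did not pass (adjusted p = 0.463 without the library labelled ZKO_Sn_Zmt replicate 1, 0.949 with all libraries). With all 12 libraries edgeR called 0 genes, with 717 at an unadjusted p under 0.05, and DESeq2 called 51. Those 717 are fewer than a share of 0.05 of the 17058 genes tested, which no difference at all would give. They show no excess of low p-values, and 0 calls do not show that nothing changed. A fit of only ZKO_Sn and ZKO called 7. Without the library labelled ZKO_Sn_Zmt replicate 1, which is in neither group but adds to the shared spread, 17 genes changed, 8 higher and 9 lower. In that fit CDH11, a mesenchymal cadherin, rose by 7.10 ± 1.05 (adjusted p = 0.0389), COL6A2 by 4.64 ± 0.72 (adjusted p = 0.0465) and PARL, a mitochondrial rhomboid protease, by 2.55 ± 0.31 (adjusted p = 0.012). DMTN, an actin-bundling protein, fell by 2.75 ± 0.38 (adjusted p = 0.0353) and CAMK2B, a calmodulin-dependent kinase, by 2.39 ± 0.38 (adjusted p = 0.0479). CDH1 differed by -0.54 ± 0.36 (adjusted p = 0.853) and was not called.

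Lists moved with 0 genes called over all genes between ZKO_Sn and ZKO. The 25 mesenchymal matrix genes were higher (2 up adjusted over the list alone; camera adjusted p = 0.00566, adjusted p = 0.902 with an estimated correlation), a call lost without ZKO replicate 1 (0.0515) or ZKO_Sn replicate 2 (0.178). The 22 TGF-beta genes were higher (2 up adjusted over the list alone; camera adjusted p = 0.0194, adjusted p = 0.588 with an estimated correlation), a call lost without ZKO_Sn replicate 1 (0.0559) or ZKO replicate 2 (0.0711). The 12 desmosome genes were lower (camera adjusted p = 0.0257, adjusted p = 0.902 with an estimated correlation), as were the 25 cell-cycle genes (camera adjusted p = 0.0281, adjusted p = 0.902 with an estimated correlation), with 0 genes in either adjusted over the list alone. Without ZKO_Sn replicate 1 or ZKO replicate 2 the desmosome genes had adjusted p of 0.132 and 0.0729 and the cell-cycle genes 0.162 and 0.37.

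ZKO_Sn_Zmt against ZKO_Sn asked what restoring Zeb1 adds to Snail. Whole chromosomes differed here too, and whether the groups differ in more than Zeb1 was not tested. The median of chromosome 8 against E was 0.37 and 0.23 in ZKO_Sn replicates 1 and 2 and -0.06 in ZKO_Sn_Zmt replicate 2. The library labelled ZKO_Sn_Zmt replicate 1 stood at 0.4, beside ZKO_Sn. On chromosome 19 the median was 0.09 and 0.12 in ZKO_Sn, 0.08 in the library labelled ZKO_Sn_Zmt replicate 1 and 0.06 in replicate 2. With all 12 libraries edgeR called 0 genes, with 517 at an unadjusted p under 0.05, and DESeq2 called 23. These 517 too are fewer than a share of 0.05 of the 17058 genes tested. ZEB1 itself was higher by 8.85 ± 2.22 and was not called. Without the library labelled ZKO_Sn_Zmt replicate 1, which holds 8 ZEB1 counts, the group is ZKO_Sn_Zmt replicate 2 alone, assumed to vary like the other groups. All directions in the rest of this comparison come from replicate 2 against ZKO_Sn. The library left out was singled out for its low ZEB1 and its closeness to ZKO_Sn. Adjusted p-values, counts of genes and list values of comparisons with ZKO_Sn_Zmt in that fit follow in part from that choice. They are therefore no independent test of the rescue. ZEB1 rose by 9.85 ± 0.92 (adjusted p = 0.00039), CDH1 fell by 4.38 ± 0.57 (adjusted p = 0.00127) and VIM rose by 1.60 ± 0.37 (adjusted p = 0.0286). COL3A1, a fibrillar collagen, rose by 10.21 ± 1.07 (adjusted p = 5e-04), CADM3, a cell adhesion molecule, by 10.28 ± 0.86 (adjusted p = 0.000166), and FBLN5, an elastic-fibre protein, by 7.72 ± 0.52 (adjusted p = 8.71e-05). WNT5A, the non-canonical Wnt ligand, rose with a ratio of 562 (155 to 4650; adjusted p = 0.000137), and its receptor ROR1 by 2.81 ± 0.66 (adjusted p = 0.0327), while of the same list VANGL2, a planar polarity gene, fell by 4.54 ± 1.03 (adjusted p = 0.0265) and SFRP1 fell by 2.67 ± 0.55 (adjusted p = 0.016); the list was not called (0.519). KRT6B, an epidermal keratin, fell by 7.30 ± 0.97 (adjusted p = 0.00146). RAB25, an epithelial recycling GTPase, fell by 6.77 ± 0.77, and ESRP1 fell by 4.87 ± 0.51 (adjusted p = 5e-04). WNT7A fell by 4.19 ± 0.58 (adjusted p = 0.00182). The count was 760 genes, 373 higher and 387 lower, against 0 without any other single library of the groups compared.

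Without the library labelled ZKO_Sn_Zmt replicate 1, 16 of 24 adhesion and polarity genes fell between ZKO_Sn_Zmt and ZKO_Sn (21 adjusted over the list alone; camera adjusted p = 2.34e-44, and 0.00128 with an estimated correlation). Of 27 matrix genes 12 rose (17 up and 1 down adjusted over the list alone; camera adjusted p = 9.06e-23, and 0.0414 with an estimated correlation). Of 23 mesenchymal markers 7 rose (8 adjusted over the list alone; camera adjusted p = 4.73e-09, and 0.013 with an estimated correlation). Of 16 epithelial regulators 8 fell (13 adjusted over the list alone; camera adjusted p = 4.62e-22, and 0.0101 with an estimated correlation). Of 15 basal markers 8 fell (12 adjusted over the list alone; camera adjusted p = 7.24e-16, and 0.013 with an estimated correlation). Desmosome genes fell in 6 of 12 cases (10 adjusted over the list alone; camera adjusted p = 5.21e-15, and 0.00456 with an estimated correlation). Cornification genes fell in 7 of 15 cases (12 adjusted over the list alone; camera adjusted p = 2.29e-14, and 0.0226 with an estimated correlation), and hemidesmosome genes in 5 of 10 (6 adjusted over the list alone; camera adjusted p = 2.39e-09, and 0.0226 with an estimated correlation). Luminal markers fell in 3 of 12 cases (1 up and 5 down adjusted over the list alone; camera adjusted p = 6.47e-05, and 0.0226 with an estimated correlation). Of 21 interferon-stimulated genes 3 rose (5 adjusted over the list alone; camera adjusted p = 0.00373, adjusted p = 0.321 with an estimated correlation). BST2, the gene of the antiviral protein tetherin, rose by 3.84. Of 13 canonical Wnt ligands and receptors 1 fell (1 adjusted over the list alone; camera adjusted p = 0.00658, adjusted p = 0.0619 with an estimated correlation). With all 12 libraries the same lists except the luminal markers were called in the same directions with 0 genes passing, at camera adjusted p from 2.75e-12 for adhesion to 0.00291 for the Wnt ligands, and 0 of them held with an estimated correlation (adjusted p from 0.232 to 0.355). In the converse fit, where the library labelled ZKO_Sn_Zmt replicate 1 alone stood for the group, the matrix list was lower (3.14e-05), and the adhesion, basal, epithelial regulator, mesenchymal, desmosome, cornification, hemidesmosome and Wnt ligand lists were not called (adjusted p from 0.0897 to 0.958). The interferon-stimulated list was higher there too (0.0331), with a list mean of -0.43 in that library against -0.69 and -0.85 in ZKO_Sn and 0.2 in replicate 2. With an estimated correlation, tried after seeing the data, neither the matrix nor the interferon list was called in the converse fit (both adjusted p = 0.587).

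The engineered groups were set against the sorted populations whose state the series text gives them. ZKO_Sn had far more CDH1 than E/M, by 8.22 ± 1.16 (adjusted p = 0.00126), and LAD1 was higher with a ratio of 18000 (3220 to 710000), GRHL2 at least 550-fold and DAPP1 at least 970-fold. In the other direction EMC10 was at least 1150-fold lower and EPDR1, an ependymin-related lysosomal protein gene, at least 203-fold lower. EMC10 was already low in ZKO, at 0.628 and 1.32 CPM in replicates 1 and 2 against 41.2 and 28.9 CPM in E. Its difference from E/M is thus not particular to ZKO_Sn. Engineered against sorted groups set a single-cell clone against sorted populations, so clone, genotype and state cannot be told apart. ZEB1 was lower at -5.55 (adjusted p = 0.0843; 0.000403 without the library labelled ZKO_Sn_Zmt replicate 1). In all 2521 genes differed, 1288 higher and 1233 lower in ZKO_Sn. The count was 1218, 788, 5255 and 893 without E/M replicate 1, ZKO_Sn replicate 1, E/M replicate 2 or ZKO_Sn replicate 2. ZKO_Sn_Zmt differed from xM in 946 genes, 598 higher and 348 lower, and in 746 without the library labelled ZKO_Sn_Zmt replicate 1, 515 higher and 231 lower. Without xM replicate 1, xM replicate 2 or ZKO_Sn_Zmt replicate 2 the count was 247, 283 and 1706. GAP43, a growth-cone protein gene, was higher in ZKO_Sn_Zmt than in xM with a ratio of 5170 (1430 to 42700), and NPTX2 lower at -9.78 ± 0.94. CDH1 was higher by 7.44 ± 1.14 (adjusted p = 0.00312; 0.0584 without xM replicate 1), and by 4.32 (adjusted p = 0.00037) without the library labelled ZKO_Sn_Zmt replicate 1. A fit of only these 2 groups called 12 genes, 4 higher and 8 lower, so most of the 946 calls rest on the spread shared with other groups. In that smaller fit the calls of CDH1 (0.141), GAP43 (0.0583) and NPTX2 (0.0604) were lost. Counts of pooled cells do not show whether the CDH1 left in ZKO_Sn_Zmt replicate 2 (9.29 CPM) comes from all cells or from a share of cells without the rescue, and this was not tested.

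Whether a step differed between the series was tested directly as a difference of differences. At the hybrid step, E/M minus E against ZKO_Sn minus ZKO, 547 genes differed, 373 in the positive and 174 in the negative direction, taken as engineered minus sorted; DESeq2 called 1210. LAD1 differed by 13.4 (adjusted p = 0.00198) and DAPP1 by 12.73 (adjusted p = 0.000845), both fitted values that depend on the prior count. CDH1 differed by 7.84 ± 1.36 (adjusted p = 0.0102), a call lost without E/M replicate 1 (0.0707), ZKO replicate 1 (0.0794) or ZKO replicate 2 (0.0734). The count of 547 was 257, 377, 160, 222, 198, 845, 164 and 235 without E replicate 1, E/M replicate 1, ZKO replicate 1, ZKO_Sn replicate 1, E replicate 2, E/M replicate 2, ZKO replicate 2 or ZKO_Sn replicate 2, and 1270 without the library labelled ZKO_Sn_Zmt replicate 1.

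At the mesenchymal step, xM minus E/M against ZKO_Sn_Zmt minus ZKO_Sn, 2 genes differed with all 12 libraries: ROBO1 at -5.68 ± 0.66 and GJA1, the gap junction protein connexin 43, at -3.43 ± 0.40 (both adjusted p = 0.0235), with 934 genes at an unadjusted p under 0.05 and 143 called by DESeq2. Both calls were lost without xM replicate 1 or 2 or ZKO_Sn replicate 1 or 2 (adjusted p 0.169 to 0.194), and that of ROBO1 also without E/M replicate 2 (0.0669); a fit of only the 4 groups lost both (0.147 for ROBO1 and 0.294 for GJA1). Without E/M replicate 1, E/M replicate 2 or ZKO_Sn_Zmt replicate 2 the count was 15, 1 and 28. Leaving out the library labelled ZKO_Sn_Zmt replicate 1 gave 381 genes, 199 in the positive and 182 in the negative direction, among them ZEB1 at 8.72 ± 1.04 (adjusted p = 0.00237), FBLN5 at 9.09 ± 0.63 (adjusted p = 0.000129) and CDH1 at -3.89 ± 0.69 (adjusted p = 0.0128), all of them engineered minus sorted.

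The log2 fold changes of the steps were correlated across genes, which are not independent replicates, to ask whether Snail alone or Zeb1 with Snail moved genes the way the sorted states differ. The family held 4 correlations. E/M enters the 2 sorted steps with opposite signs, and ZKO_Sn enters the Snail and rescue steps likewise. A bias of those libraries would push the paired correlations in opposite directions, so opposite signs between them are not separate results. E/M against E correlated with ZKO_Sn against ZKO at r = 0.205 (Spearman rho = 0.333; SD 0.111 and range -0.065 to 0.339 over the 16 ways of taking 1 library per group). It correlated with ZKO_Sn_Zmt against ZKO_Sn at r = 0.319 (rho = 0.088; SD 0.296, range -0.213 to 0.571). xM against E/M correlated with ZKO_Sn against ZKO at r = -0.104 (rho = -0.305; SD 0.171, range -0.354 to 0.287) and with ZKO_Sn_Zmt against ZKO_Sn at r = 0.154 (rho = 0.272; SD 0.114, range -0.109 to 0.338). Leaving out the library labelled ZKO_Sn_Zmt replicate 1, the 4 values were 0.191, 0.44, -0.091 and 0.112 in that order. The correlation of E/M against E with the rescue step was -0.133 without ZKO_Sn_Zmt replicate 2, so its sign rests on that library, and that of xM against E/M with the Snail step was 0.02 without E/M replicate 1. CDH1, for example, fell in E/M and in ZKO_Sn_Zmt replicate 2 and was not called in ZKO_Sn, and ROBO1 differed between the series at the mesenchymal step.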

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

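The 4 tests on the library labelled ZKO_Sn_Zmt replicate 1, the tests of the transcripts of E and xM cells in each E/M library, the mixes and the correlation with xM minus E/M, the single-library tests of named genes, the test of GC content and length as the whole cause, and the test of copy number as the whole cause were chosen after the results were seen.

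Steps that differed between the sorted and the engineered series drew attention because the difference itself was tested and passed. At the hybrid step 547 genes did so; their fitted log2 differences, engineered minus sorted, included CBLC at 14, GRHL2 at 13.75, LAD1 at 13.4, DAPP1 at 12.73, CDH1 at 7.84, CRMP1 at -11.51, MAP1LC3A at -10.93, GGT5 at -10.71 and RTN1 at -10.09, where values of genes near 0 counts depend on the prior count. LAD1 and DAPP1 kept their calls on leaving out each library of the 4 groups. CBLC, GRHL2 and CDH1 lost theirs without E/M replicate 1 (adjusted p 0.0689, 0.0656 and 0.0707), ZKO replicate 1 (0.0804, 0.0794 and 0.0794) or ZKO replicate 2 (0.077, 0.0711 and 0.0734). Dropping ZKO replicate 2 also ended the calls of CRMP1 (0.106), RTN1 (0.0911), GGT5 (0.0865) and MAP1LC3A (1, at a difference of -7.29), and dropping ZKO replicate 1 those of CRMP1 (0.102) and MAP1LC3A (0.0539). GGT5 and MAP1LC3A were also lost without E replicate 1 (0.0725 and 0.0772), E replicate 2 (0.0538 and 0.12), ZKO_Sn replicate 1 (0.0802 and 0.08) or ZKO_Sn replicate 2 (0.0729 and 0.0944). At the mesenchymal step 2 genes did so, ROBO1 at -5.68 and GJA1 at -3.43, and both were lost without either library of xM or ZKO_Sn (0.169 to 0.194), ROBO1 also without E/M replicate 2 (0.0669).

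The library labelled ZKO_Sn_Zmt replicate 1 lacks ZEB1 and lies next to ZKO_Sn. A swap of labels with a ZKO_Sn library needs a ZKO_Sn library with high ZEB1, and the higher of the 2 had 0.217 CPM, which argues against it; too few reads is argued against by the 497 reads that 10 CPM of ZEB1 would have given at its depth. A library of ZKO_Sn cells under a wrong label may be the source: its distance of 0.241 to ZKO_Sn replicate 1 is below the 0.375 between the ZKO_Sn libraries. Its distance to ZKO_Sn replicate 2 was 0.52, above that value, so a shared replicate number may add to the closeness. The library's cell-cycle list mean was -0.72, against -0.1 and 0.09 in ZKO_Sn replicates 1 and 2. Its adhesion list mean lay nearer, at -0.29 against -0.42 and -0.57. With GC and length trends removed, its medians against E on chromosomes 8 and 3 were 0.4 and 0.27, picked after they were seen. ZKO_Sn replicates 1 and 2 had 0.37 and 0.23 on chromosome 8 and 0.25 and 0.29 on chromosome 3. ZKO_Sn_Zmt replicate 2 had -0.06 and 0.13. On chromosome 19 the library stood at 0.08 and replicate 2 at 0.06. Whether this separates a wrong label from cells without the construct was not tested. Its ZEB1 level of 0.163 CPM fits equally with rescued cells that lost or never expressed the construct, and that biological explanation cannot be told apart from the wrong label, since cells without the construct have the ZKO_Sn genotype. Leaving this library out moved the rescue comparison from 0 to 760 called genes.

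The 2 E/M libraries differ at a distance of 0.964, more than any other 2 libraries of a group. The correlation of 0.032 of their difference with xM minus E decides nothing on E or xM cells in 1 of them, since E/M and xM differ from E in much the same genes (r = 0.815); for xM cells in replicate 2 speak its distance of 0.568 to xM replicate 2, a correlation of 0.525 with xM minus E/M (0.018 with GC and length trends removed), and a mix of replicate 1 with an xM share of 0.8 that takes the distance down to 0.544. Such cells would bring all their abundant transcripts, and those low in the other E/M library argue against either as the main source: the ones of E stood at a median of 0.0158 of their E level or less, and the 15 and 12 of xM at 0.0763 and 0.0321 of their xM level in replicates 1 and 2, where the nearest mixes need an xM share of 0.29 and 0.8, so a smaller share stays open. GC content and transcript length explained an R squared of 0.551 of their difference over 9466 genes, more than in any other group, so library preparation is a candidate cause, but not all of it: with that trend removed the distance was 0.646, above the 0.459 of E treated alike but below the 0.835 of ZKO_Sn_Zmt, whose libraries differ in ZEB1 and were left out of this comparison, so E/M is then no longer the furthest apart of all groups. No biological explanation was tested, since the labels give both libraries the same description.

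The 2848 genes called in E/M and 1600 in xM separate them from E, and copy-number differences between the populations may add to them. The largest chromosome median shared by both replicates of a population was a log2 difference of 0.49, where random gene sets of the same sizes reached 0.18 at most. Copy number of whole chromosomes as the whole cause is argued against by the 66.5% of called genes past 2-fold in E/M that lie on chromosomes whose median stayed within 0.15 of 0. The share of all genes on those chromosomes was not set beside it. A chromosome median does not show copy-number changes of smaller regions, so these stay open. DNA was not analysed here, and regulation of whole domains stays open beside copy number, as does the difference of state that the sort was made for.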

How the results depend on the processing

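The fits without the library labelled ZKO_Sn_Zmt replicate 1 for contrasts that do not use it, the removal of GC and length trends, and the single-library tests of named genes were chosen after the results were seen. All counts of changed genes stayed within 1.5-fold under RLE scaling and the stricter filter. The cause of each difference below was not tested, except that a test against a 2-fold change, a fit of fewer libraries and a single library left in a group change the counts by construction. Where leaving out a library left 1 in its group, the lone library was assumed to vary like the other groups.

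Order below: E/M against E, xM against E/M, xM against E, Snail step (ZKO_Sn against ZKO), rescue step (ZKO_Sn_Zmt against ZKO_Sn), ZKO against E, ZKO_Sn against E/M, ZKO_Sn_Zmt against xM, difference at the hybrid step, difference at the mesenchymal step. Main counts were 2848, 99, 1600, 0, 0, 5, 2521, 946, 547 and 2. Leaving out single libraries gave 815 to 5632, 10 to 2829, 542 to 2305, 0 to 17, 0 to 760, 0 to 14, 788 to 5255, 247 to 1706, 160 to 1270 and 0 to 381. A fit of only the groups compared gave 1897, 18, 2940, 7, 0, 42, 2039, 12, 1077 and 0. A test against a 2-fold change gave 1163, 38, 931, 0, 0, 3, 1131, 530, 337 and 0. Without a low-count filter the counts were 3782, 673, 2494, 130, 300, 81, 3477, 1826, 1518 and 379, and by DESeq2 3683, 522, 2164, 51, 23, 29, 3324, 1471, 1210 and 143. Removal of GC and length trends gave 59 for xM against E/M, 2443 for xM against E and 5 for the difference at the mesenchymal step, and the others within 1.5-fold; in xM against E/M it moved the split from 63 higher and 36 lower to 44 and 15, and in ZKO_Sn against E/M the median of all genes was -0.107 with trends removed and -0.008 before. Replicate number as a block gave 3434, 103, 1900, 2, 0, 2, 2944, 1029, 580 and 3, and with it EMC10 in ZKO against E had an adjusted p of 0.0551. Of the 15 correlations of replicate differences between groups, from 0 to 0.53, 11 were over 0.1 and 4 were not, so the numbers were not taken to pair the libraries; a batch shared by number stays open, since all 6 second replicates held more mitochondrial counts.

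Genes higher in E/M than in both E and xM numbered 20, with 156 without a filter, 143 by DESeq2, 7 with GC and length trends removed, 5 against a 2-fold change and 0 to 940 on leaving out single libraries. The correlation of E/M against E with the Snail step was 0.079 without a filter and 0.333 by rank. That with the rescue step was 0.123 without a filter and -0.133 to 0.44 on leaving out single libraries, reversed without ZKO_Sn_Zmt replicate 2. Without a filter, xM against E/M correlated at -0.031 with the Snail step and at 0.048 with the rescue step. The correlation of xM against E/M with the Snail step was -0.305 by rank, reversed to 0.028 with GC and length trends removed and to 0.02 without E/M replicate 1, and was -0.16 at the lowest on leaving out a library; that with the rescue step was 0.272 by rank and 0.411 in genes called between xM and E/M.

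Of 48 list calls, 20 held by fry, which called 23 lists in all, and 0 with an estimated correlation. With GC and length trends removed 5 calls were lost, by camera adjusted p. They were mitochondrial genes in E/M against E (0.0678) and canonical Wnt ligands and receptors in xM against E/M (0.0811). The rest were inflammatory (0.0522) and matrix genes (0.0901) in xM against E, and interferon-stimulated genes in ZKO against E (0.061). On leaving out ZKO_Sn_Zmt replicate 2 from the rescue step the directions of 5 lists reversed: basal markers (adjusted p 0.958), adhesion (0.0897), epithelial regulators (0.387), mesenchymal markers (0.387) and matrix (3.14e-05). The other end of their ranges on leaving out single libraries was 7.24e-16, 2.34e-44, 4.62e-22, 4.73e-09 and 9.06e-23, and the matrix list reached 0.0333 without ZKO_Sn replicate 1. The immediate early list in ZKO against E reversed without E replicate 1 (0.00885), with 6.18e-24 to 0.0322 otherwise. LTB in the rescue step went from 1.43 without ZKO_Sn_Zmt replicate 2 to -6.86 without the library labelled replicate 1, and ZEB1 in ZKO_Sn_Zmt against xM from 3.18 to -6.88 on leaving out the library labelled replicate 1 or replicate 2. Calls of a named gene in a comparison numbered 143, and 223 without the library labelled ZKO_Sn_Zmt replicate 1. Of 258 results of a named gene in a comparison, 258 kept their side of the threshold under RLE scaling, 245 with GC and length trends removed (12 lost and 1 gained a call) and 239 by DESeq2 (19 gained a call). Among the 12 lost were SNAI1 and ESAM in E/M against E (adjusted p = 0.0769 and 0.0576 by edgeR's quasi-likelihood test). On simulated counts 2-fold changes were recovered at 2 to 8% with these replicate numbers, so small changes are mostly beyond reach.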

Other observations

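The values here were picked after they were seen, and the transcription factor list they come from was written before the data were examined.

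Of 17 listed transcription factors of epithelial-mesenchymal transition, a list without ZEB1 and SNAI1, 1 rose and 3 fell from E to E/M, and 3 rose and 1 fell from E to xM. ZEB2, the paralog of ZEB1, stood at 0.05 and 0.0449 CPM in E replicates 1 and 2, 0.515 and 3.49 CPM in E/M and 9.51 and 11.7 CPM in xM; it was higher in xM than in E by 7.73 (adjusted p = 0.0192) and not called in E/M against E (adjusted p = 0.0538). KLF8, a repressor of CDH1, fell from E to E/M by 6.49 (adjusted p = 0.000138 by edgeR's quasi-likelihood test), and SNAI2, the Slug gene, by 1.47 (adjusted p = 0.025). FOXC2, a mesenchyme regulator, was the riser of that step at 2.53 (adjusted p = 0.0122). In ZKO_Sn_Zmt replicate 2 against ZKO_Sn, without the library labelled ZKO_Sn_Zmt replicate 1, ZEB2 rose by 6.63 (adjusted p = 0.00127).

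PARL averaged 50.7 CPM in ZKO and 298 CPM in ZKO_Sn, and stood at 467 CPM in the library labelled ZKO_Sn_Zmt replicate 1 and 132 CPM in replicate 2. Of the leukocyte markers in E/M against E, LAPTM5, a lysosomal protein gene of blood cells, rose by 4.36 (adjusted p = 0.000594) and CD14, the lipopolysaccharide co-receptor gene, by 3.7 (adjusted p = 0.00459), while CSF1R, a macrophage growth factor receptor gene, fell by 3.00 (adjusted p = 0.0118), all by edgeR's quasi-likelihood test.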
